A study of Mus musculus with 12 samples.

How the data were processed

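RNA was measured in the prefrontal cortex and the hippocampus of adult female mice aged 38 to 40 weeks, on 12 Affymetrix arrays, 1 per tissue sample. The labels give 2 genotypes, both without APLP2, a relative of the amyloid precursor protein APP. APLP2-KO mice carry intact App alleles, and APPsα-DM mice carry in addition an edited App on both alleles. In the edited allele, as it is generally described, a stop codon after the alpha-secretase site leaves only the secreted ectodomain APPsα. The genotypes and tissues made 4 groups of 3 arrays, and the series design gives 3 mice per genotype. Per the labels, 6 generations of back-crossing to C57BL/6 preceded the study, and no wild-type sample was analysed here. Per the labels' protocols, total RNA was prepared with a column kit, its quality was checked by capillary electrophoresis, and biotin-labelled cRNA was made from 1 µg.

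Per the submitters' processing notes, RMA and the affy package were used, whose versions are not given in the sources used here. RMA corrects the background, normalises arrays by quantiles and summarises the probes of each probe set. The deposited values were on a log2 scale and ranged from 1.80 to 14.36, with none missing. Whether all arrays were normalised together is not stated, but the array medians lay between 5.86 and 5.91, the lower quartiles between 4.19 and 4.27 and the upper quartiles between 7.99 and 8.05. The table held 45101 probe sets, of which 64 control probe sets were left out and 45037 were tested without a filter on dim signals. Gene symbols came from the platform annotation: 34945 probe sets had 1 symbol, 932 had several and 9160 had none, and only the first kind was named as a gene. Of these, 34741 matched a gene of the reference table (assembly GRCm38.p6), which gave current symbols, chromosomes and gene order, and 204 did not match and kept the symbol of the annotation. Gene positions of that reference served for gene order and distance from App, and no coordinates are printed, because the build behind the probe annotation is not given in the sources used here.

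All tests were run in R 4.3.3 with limma 3.58.1 on the deposited log2 values. For each probe set, lmFit fitted the means of the 4 groups over all 12 arrays (8 residual degrees of freedom) and eBayes moderated the variances (4.25 prior degrees of freedom). Contrasts gave APPsα-DM minus APLP2-KO in each tissue, the difference between these effects (hippocampus minus cortex), and hippocampus minus cortex in each genotype. A mean genotype effect was fitted on the average of the cortex and hippocampus values of each genotype and replicate number, 3 against 3. Benjamini-Hochberg adjustment ran over the 45037 probe sets, with a threshold of 0.05 on the adjusted p. Every adjusted p of a gene is limma's, two-sided, and errors of log2 differences are the moderated standard errors (SE). Exact permutation tests of single values used 3 against 3 arrays and cannot give a two-sided p below 0.1. The number of arrays limits the precision: the median SE of a genotype difference within a tissue was 0.0938 on the log2 scale, and 0.0662 for the mean effect.

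The 32 gene lists covered APP and its processing, synapses, neuronal and non-neuronal cell types, neighbouring tissues that a dissection can include, metabolism, stress and the chromosomal surroundings of App and Aplp2. They were tested with limma's camera at a preset inter-gene correlation of 0.01, with 1 probe set per gene (the highest mean), and adjusted over the 32 lists. Alternatives were camera with the correlation estimated from the data and fry, which tests whether the genes of a list move, on balance, in 1 direction. Members were also adjusted over the list alone. The comparisons, tests, lists, rule for named genes and most alternatives were fixed before the data were examined. List tests of the difference between tissues and of the tissue comparisons, a choroid plexus covariate, and leaving out 2 cortex arrays with a high Ttr signal were chosen after seeing the data. So were the settings for genes near App that left out App, took the whole of chromosome 16, or did both.

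Named genes followed a rule. For each genotype comparison, every gene past the threshold was to be named if there were 24 or fewer, with the smallest p values added up to 24 candidates, of which any could be named as not past the threshold. For the tissue comparisons, the candidates were the 12 largest rises and 12 largest falls past the threshold without overlap of the groups in both genotypes, and for the difference between tissues the 10 smallest p values. App, Aplp1 and Aplp2 were always reported, and from each list its members past the threshold or up to 4 with the smallest p. A probe set that has no gene in the annotation used here was reported as unnamed because it was among the few that passed. Probe sets of a gene are counted in order of their identifier, 1 to 4 for App, 1 to 2 for Aplp1 and 1 to 5 for Aplp2. The genes named among other calls in the part on settings were chosen after their values were seen.

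The replicate numbers come from the sample titles, and the sources used here do not state which arrays share an animal. As a check, the residuals of arrays with the same number were correlated across probe sets. Between cortex and hippocampus of APLP2-KO the correlations were 0.109, 0.131 and 0.155, all above the minimum of 0.1 set for pairing, so the tissue comparison in APLP2-KO was also read with number as a block. For APPsα-DM they were 0.0785, 0.0193 and 0.0372, below that minimum.

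The steps were tested on simulated data with known changes. Probe sets were changed together by 0.5, 1, 1.5 or 2 log2, 50 of each. Of the 50 changed by 0.5 log2, 64% were recovered in cortex, 60% in hippocampus and 72% for the mean effect. At a change of 1 log2, 98% were recovered in cortex, 98% in hippocampus and 100% for the mean effect. So many true changes make the adjusted threshold easier to pass than in the data, where few probe sets were called. These shares are thus no estimate of what was detectable in the data. For an unchanged list, 30 genes shared a factor between arrays with an SD of 0.5 log2. Its unadjusted p was under 0.05 in 36 of 50 draws with the preset correlation and in 1 of 50 with the estimated one. That factor was wider than the within-group SD of the mean score of the cholesterol list (0.0193 to 0.107) and narrower than that of the choroid plexus list (0.717 to 1.27). The shares of draws are thus no estimate of false calls among the lists tested. Further alternatives were a filter on dim probe sets, cyclic loess, median centring, a trended robust variance prior, array weights, other thresholds, only the 6 arrays compared, replicate number as a fixed or random block, and leaving out each array in turn.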

Results

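The data set comprised 12 expression arrays of mouse brain, 3 each of APLP2-KO cortex, APLP2-KO hippocampus, APPsα-DM cortex and APPsα-DM hippocampus. Both genotypes lack APLP2, so that the comparison of APPsα-DM with APLP2-KO addresses what the loss of membrane-bound APP, with only its secreted ectodomain left, does to gene expression. Tissue was the main source of variation: the leading principal component held 53.7% of the variance and separated hippocampus from cortex, and the next held 8.26%. Arrays of the same group correlated at r = 0.9947 to 0.9972 over all probe sets (12 pairs). Arrays of the same tissue but other genotype correlated at 0.9949 to 0.9973 (18 pairs), and arrays of different tissues at 0.987 to 0.992 (36 pairs).

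The signal of App, the edited gene, was far lower in APPsα-DM in both tissues. In cortex, App probe set 1 (chromosome 16; probe sets of a gene are counted in order of identifier) fell from 12.63 ± 0.13 to 7.96 ± 0.25 log2 units (mean ± SD, n = 3 each), a difference of -4.67 ± 0.11 (SE) or 25.4-fold (adjusted p = 5.9e-10). In hippocampus it fell from 12.53 ± 0.06 to 7.93 ± 0.06, by -4.60 ± 0.11 (adjusted p = 7.06e-10). App probe set 2 fell less, by -1.67 ± 0.07 in cortex (3.17-fold, adjusted p = 1.62e-07) and by -1.91 ± 0.07 in hippocampus (3.76-fold, adjusted p = 3.1e-08). The other App probe sets were dim in every group: probe set 3 differed by -0.11 in cortex and 0.05 in hippocampus at a level of 2.64 in APLP2-KO cortex, and probe set 4 by -0.35 and -0.19, none past the threshold. Where these probes lie relative to the edit was not analysed here. The signal therefore cannot tell less App RNA from a loss of probe target in the edited allele. The genotype labels of the 12 arrays were each matched by App, since the arrays of the genotypes did not overlap for either bright probe set.

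Aplp1 and Aplp2, the relatives of App, did not differ detectably between the genotypes. The Aplp1 probe sets 1 and 2 differed by -0.06 and -0.06 in cortex and by 0.04 and -0.02 in hippocampus. The 5 Aplp2 probe sets differed by -0.27 to -0.03 in cortex and by -0.08 to 0.00 in hippocampus, with adjusted p of at least 0.999 for every one of these. Aplp2 is knocked out in both genotypes, yet Aplp2 probe set 1 read 10.08 in APLP2-KO cortex and 10.06 in APPsα-DM cortex. Without a wild type, and with the position of the probes relative to the deletion not analysed here, this signal checks nothing about the knockout.

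**Figure D1:**
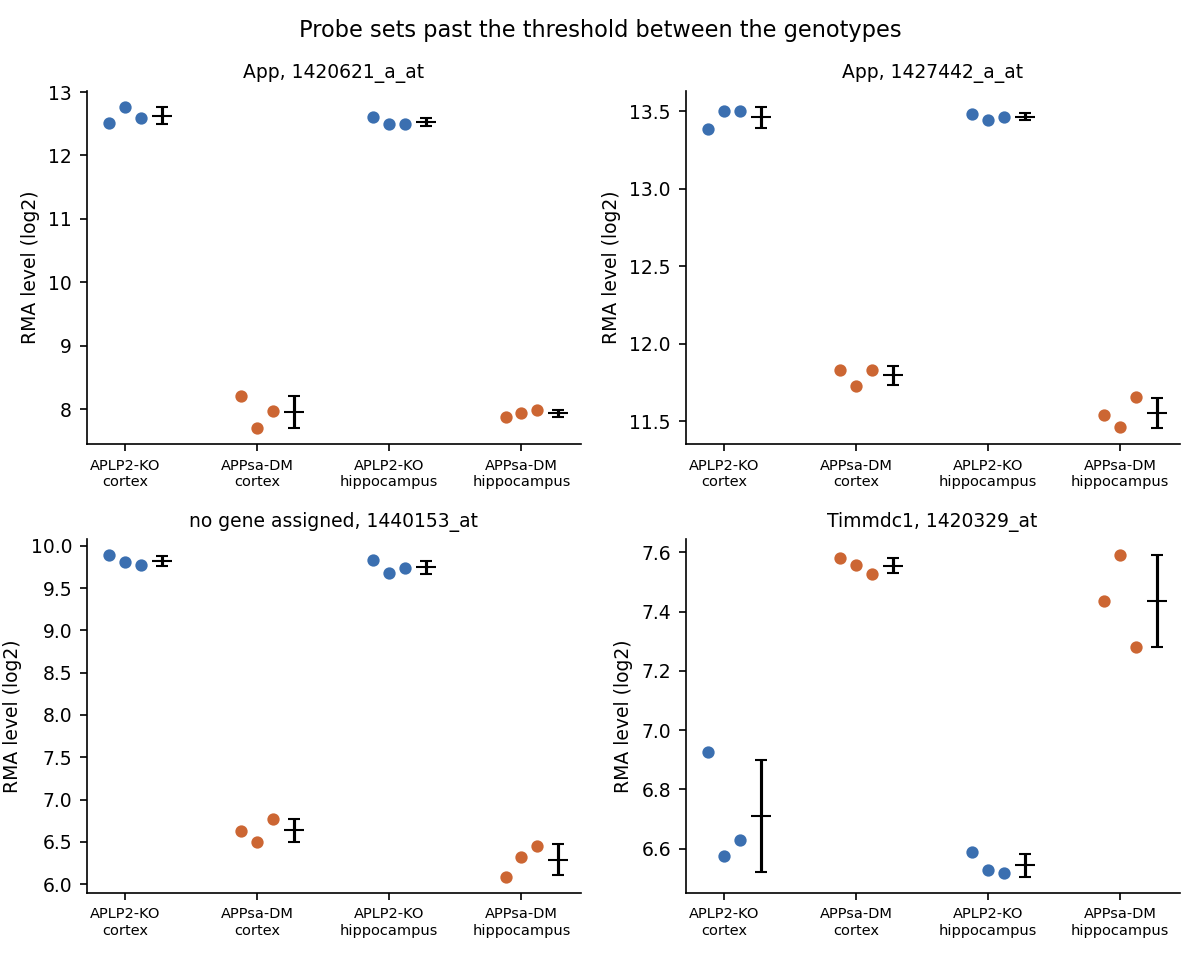
Log2 expression per array (points) with group mean and SD (bars, n = 3) for App probe sets 1 and 2, the called probe set without a gene name and Timmdc1, in cortex and hippocampus of APLP2-KO and APPsα-DM. In cortex, App probe set 1 reads 12.63 against 7.96 and Timmdc1 6.71 against 7.56, and for none of the 4 probe sets do the arrays of the genotypes overlap within a tissue.

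In prefrontal cortex, the signal of 2 genes differed between APPsα-DM and APLP2-KO: that of App was lower and that of Timmdc1 was higher. Timmdc1, which encodes an assembly factor of mitochondrial complex I and lies like App on chromosome 16, rose from 6.71 ± 0.19 to 7.56 ± 0.03, by 0.84 ± 0.10 or 1.80-fold (adjusted p = 0.0162, n = 3 each, arrays not overlapping). The array holds no other probe set of Timmdc1. A probe set without a gene name in the annotation used here fell from 9.82 to 6.64, by -3.19 ± 0.10 or 9.12-fold (adjusted p = 5.81e-09). Together with the 2 App probe sets these were the 4 calls among 45037, 1 higher and 3 lower, and 2027 probe sets (4.50%) had an unadjusted p under 0.05 against 2251.85 expected by chance. The genes next in line did not pass: Cdk5rap1, which encodes an RNA-modifying enzyme, differed by -0.60 ± 0.11, Prokr2, a neuropeptide receptor gene, by 0.53 ± 0.10, and a probe set of Upk1b by -0.49 ± 0.09 (adjusted p = 0.612 each). Trib1 differed by -0.43 ± 0.08 (adjusted p = 0.620), Slc35a5 by -0.39 ± 0.08 (adjusted p = 0.641) and Camk2n2, which encodes an inhibitor of the kinase CaMKII, by -0.37 ± 0.07 (adjusted p = 0.735). The Timmdc1 call ended when single arrays were left out: the adjusted p was 0.133 without APLP2-KO cortex 2, 0.170 without APLP2-KO cortex 3, 0.156 without APPsα-DM cortex 1, 0.137 without APPsα-DM cortex 2 and 0.112 without APPsα-DM cortex 3. It was 0.209 with only the 6 cortex arrays and 0.577 without the 2 cortex arrays high in Ttr, and over all settings the Timmdc1 difference stayed between 0.78 and 0.95 with an adjusted p from 0.00309 to 0.577.

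Of the 32 gene lists, 8 were called in cortex at the preset correlation and 0 with the estimated correlation, where the smallest adjusted p was 0.867 and 0 lists had an unadjusted p under 0.05. Fry called 2 lists, APP family and its secretases (adjusted p = 0.00787) and proposed APP intracellular domain target genes (adjusted p = 0.0440), both of which hold App. Among all list members only App fell over all genes tested, and it stands in 3 lists. Adjusted over the list alone, Bace2, a secretase gene, was higher by 0.36 ± 0.10 (adjusted p = 0.0248). It also stands in the fixed list of genes around App on chromosome 16. Cux1, an upper-layer marker, and Tnnt1, a marker of thalamus, adjusted likewise, were lower by -0.26 ± 0.06 (adjusted p = 0.0321) and -0.59 ± 0.15 (adjusted p = 0.0327). These 3 did not pass over all genes, and Tnnt1 was at -0.38 without APLP2-KO cortex 1.

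Genes of cholesterol synthesis and uptake were lower in APPsα-DM cortex: 22 of 23 lay below 0, with a median of -0.12 (adjusted p = 2.34e-06; adjusted p = 0.867 with an estimated correlation). Idi1 differed by -0.26 ± 0.10, Stard4 by -0.26 ± 0.12 and Insig1, a sensor of the sterol pathway, by -0.23 ± 0.10. This list kept its call without any of the 6 arrays in turn but was not called by fry (adjusted p = 0.473). Its mean score per array separated the genotypes (two-sided exact p = 0.1, the smallest possible). Striatal neuron markers were higher, 17 of 18 above 0 with a median of 0.21 (adjusted p = 2.14e-05; adjusted p = 0.867 with an estimated correlation), with Pdyn at 0.36 ± 0.12 and Sh3rf2 at 0.52 ± 0.20. Without APLP2-KO cortex 3 the adjusted p of the striatal list was 0.0695 and without APPsα-DM cortex 3 it was 0.172. Without APLP2-KO cortex 3, Pdyn was at 0.22 and Sh3rf2 at 0.30, and Sh3rf2 was at 0.31 without the 2 cortex arrays high in Ttr. The mean score of the striatal list per cortex array ran from 0.731 to 1.37 and did not separate the genotypes (two-sided exact p = 0.3). Whether the share of striatal tissue differed between the cortex pieces was not tested.

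Activity-regulated immediate early genes were lower in cortex, 24 of 34 below 0 with a median of -0.15 (adjusted p = 0.00182; adjusted p = 0.867 with an estimated correlation). Arc, a synaptic activity marker, differed by -1.45 ± 0.51, Per1 by -0.53 ± 0.18 and Jun by -0.44 ± 0.14. The call ended without APLP2-KO cortex 1 (adjusted p = 0.467), where Arc was at -0.89 and Jun at -0.27, and without APPsα-DM cortex 2 (adjusted p = 0.0639), where Per1 was at -0.29. Per1 was at -0.27 without the 2 cortex arrays high in Ttr. In the same direction, 25 of 39 genes of synaptic vesicle release lay below 0 (adjusted p = 0.0332; adjusted p = 0.867 with an estimated correlation), with Vamp2 at -0.22 ± 0.08 and Stx1a at -0.21 ± 0.08. That call ended without APLP2-KO cortex 2 (0.180) and APPsα-DM cortex 2 (0.531). Astrocyte markers were also lower, 20 of 27 below 0 (adjusted p = 0.0332; adjusted p = 0.867 with an estimated correlation), with S100b at -0.19 ± 0.08 and Fgfr3 at -0.18 ± 0.08, and the call ended without APLP2-KO cortex 1 (0.501), APLP2-KO cortex 2 (0.0932) or APPsα-DM cortex 1 (0.373). S100b was at -0.12 without APLP2-KO cortex 1 and at -0.31 without the 2 cortex arrays high in Ttr.

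Markers of endothelial cells and pericytes were higher in cortex, 20 of 25 above 0 (adjusted p = 0.0332; adjusted p = 0.871 with an estimated correlation), with Itm2a at 0.32 ± 0.10 and Kdr, a receptor of vascular growth factor, at 0.33 ± 0.13. The endothelial call ended without APLP2-KO cortex 2 (0.104), APLP2-KO cortex 3 (0.591), APPsα-DM cortex 2 (0.396) or APPsα-DM cortex 3 (0.0522), and with the mean of all probe sets of a gene (0.136). Kdr was at 0.18 without APPsα-DM cortex 2 and at 0.08 without the 2 cortex arrays high in Ttr. Genes of adult neurogenesis were higher, 16 of 21 above 0 (adjusted p = 0.0332; adjusted p = 0.867 with an estimated correlation), with Draxin at 0.24 ± 0.10, and lost the call without APLP2-KO cortex 1 (0.119), APLP2-KO cortex 2 (0.132) or APPsα-DM cortex 3 (0.304). Genes of GABAergic neurons and synapse were higher, 15 of 22 above 0 (adjusted p = 0.0445; adjusted p = 0.867 with an estimated correlation), with Gad1, which makes GABA, at 0.19 ± 0.08 and Dlx1 at 0.34 ± 0.13. That call ended without APLP2-KO cortex 1 (0.111), APLP2-KO cortex 3 (0.167), APPsα-DM cortex 1 (0.0519) or APPsα-DM cortex 3 (0.440), and with the mean of all probe sets of a gene (0.195), and without APPsα-DM cortex 3 Gad1 was at 0.11 and Dlx1 at 0.18. APPsα-DM cortex 3 had the highest cortex score of the GABAergic list (0.255) and of the striatal list (1.37), whose call also ended without it (0.172). The GABAergic score separated the genotypes in cortex (two-sided exact p = 0.1, the smallest possible). Glutamatergic postsynapse (adjusted p = 0.414), long-term potentiation and calcium signalling (0.355), oligodendrocytes and myelin (0.414), microglia (0.414), choroid plexus (0.614) and the other lists were not called in cortex, with adjusted p from 0.186 to 0.977.

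In hippocampus, the same 4 probe sets were called as in cortex: App fell, as given above, Timmdc1 rose and the same unnamed probe set fell. Timmdc1 rose from 6.54 ± 0.04 to 7.44 ± 0.16, by 0.89 ± 0.10 or 1.85-fold (adjusted p = 0.00909, n = 3 each, arrays not overlapping). The unnamed probe set fell from 9.75 to 6.29, by -3.46 ± 0.10 (adjusted p = 2.16e-09). These were the 4 calls among 45037, 1 higher and 3 lower, and 1852 probe sets (4.11%) had an unadjusted p under 0.05. Not past the threshold were B9d1 and Foxj1, both genes of cilia, at 0.54 ± 0.08 (adjusted p = 0.186) and 0.49 ± 0.10 (0.626), with Efcab7 at 0.43 ± 0.08 (0.626) and Cfap52 at 0.61 ± 0.13 (0.724). Cdk5rap1 differed by -0.70 ± 0.11 (0.197), Ccdc80 by 0.73 ± 0.13 (0.508), Slc35a5 by -0.40 ± 0.08 (0.626) and Senp7 by -0.31 ± 0.07 (0.769). Igfbp6 and the growth factor gene Pdgfd differed by 0.80 ± 0.16 and 0.85 ± 0.17 (0.711 each), and the endothelial gene Clec14a by 0.52 ± 0.10 (0.650). The Timmdc1 call ended without APLP2-KO hippocampus 2 (0.0894), APLP2-KO hippocampus 3 (0.0880), APPsα-DM hippocampus 1 (0.0717) or APPsα-DM hippocampus 2 (0.0597) and with only the 6 hippocampus arrays (0.134), while its difference stayed between 0.81 and 0.97 over all settings, with an adjusted p from 0.00167 to 0.134.

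In hippocampus 6 lists were called at the preset correlation, 0 with the estimated correlation (smallest adjusted p = 0.613, 2 lists at an unadjusted p under 0.05) and 2 by fry, APP family and its secretases (adjusted p = 0.00434) and chromosome 9 neighbourhood of Aplp2 (adjusted p = 0.0180). Endothelial and pericyte markers were higher, with 25 of 25 genes above 0 and a median of 0.17 (adjusted p = 4.5e-10; adjusted p = 0.613 with an estimated correlation). Tie1 differed by 0.44 ± 0.14, Kdr by 0.41 ± 0.13 and Pecam1 by 0.28 ± 0.09, each with an adjusted p = 0.0747 over the list alone. Cholesterol synthesis and uptake was lower, 21 of 23 below 0 with a median of -0.15 (adjusted p = 1.98e-08; adjusted p = 0.613 with an estimated correlation), with Idi1 at -0.31 ± 0.10, Sqle at -0.25 ± 0.10 and Msmo1 at -0.24 ± 0.08. Both lists kept their call without any of the 6 arrays in turn, but neither was called by fry (adjusted p = 0.319 each). The mean score separated the genotypes for the endothelial list (two-sided exact p = 0.1, the smallest possible) and not for the cholesterol list (exact p = 0.2). In both tissues, App was again the only list member to change over all genes tested, and adjusted over the list alone no further hippocampal member passed.

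Choroid plexus markers were higher in APPsα-DM hippocampus, with 23 of 23 genes above 0 and a median of 0.78 (adjusted p = 3.13e-06; adjusted p = 0.966 with an estimated correlation), and Clic6 at 1.15 ± 0.65. Ttr, the most abundant choroid plexus transcript, ran from 8.20 to 14.36 over the 12 arrays and was 10.63, 13.43 and 14.21 in APLP2-KO hippocampus 1, 2 and 3 against 14.34, 11.83 and 14.36 in APPsα-DM hippocampus 1, 2 and 3. The choroid score did not separate the genotypes in hippocampus (two-sided exact p = 0.3) or cortex (exact p = 0.5). Without APPsα-DM hippocampus 1 the adjusted p of the choroid list was 0.206. Clic6 was at 0.60 without that array, at 1.97 without APPsα-DM hippocampus 2 and at 0.34 with the choroid score as a covariate. Smooth muscle, leptomeninges and fibroblasts were higher, 19 of 23 above 0 with a median of 0.27 (adjusted p = 0.00165; adjusted p = 0.966 with an estimated correlation), with Myh11 at 0.41 ± 0.14 and Mylk at 0.27 ± 0.10. Without APPsα-DM hippocampus 1 this list turned and was called lower (adjusted p = 0.00210), with Myh11 at 0.24, and Myh11 was at 0.27 without APLP2-KO hippocampus 2.

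Immediate early genes were lower in hippocampus, 25 of 34 below 0 with a median of -0.17 (adjusted p = 0.000174; adjusted p = 0.928 with an estimated correlation), with Egr1 at -0.62 ± 0.17 (adjusted p = 0.0999 over the list alone) and Egr4 at -0.34 ± 0.11. Without APLP2-KO hippocampus 1 the adjusted p was 0.160 and Egr4 was at -0.22. Genes of the respiratory chain were slightly higher, 40 of 47 above 0 with a median of 0.03 (adjusted p = 0.0255; adjusted p = 0.966 with an estimated correlation) and Sdhc at 0.11 ± 0.07, and lost the call without APLP2-KO hippocampus 2 (0.105), APLP2-KO hippocampus 3 (0.390), APPsα-DM hippocampus 1 (0.104) or APPsα-DM hippocampus 3 (0.102), and with the mean of all probe sets of a gene (0.0833), and Sdhc was at 0.06 without APPsα-DM hippocampus 1 and with the choroid covariate. With the choroid score as a covariate, tested at the preset correlation only, the choroid list (0.790), the immediate early genes (0.113), smooth muscle (0.111) and the respiratory chain (0.159) were no longer called, whereas the endothelial list (1.98e-07) and the cholesterol list (2.46e-05) were, and GABAergic neurons and synapse, at 0.0618 before, reached 0.00919. Astrocytes (0.128), oligodendrocytes and myelin (0.133), APP family and its secretases (0.163), microglia (0.216), synaptic vesicle release (0.950) and the other lists were not called, with adjusted p from 0.0618 to 0.950.

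**Figure D2:**
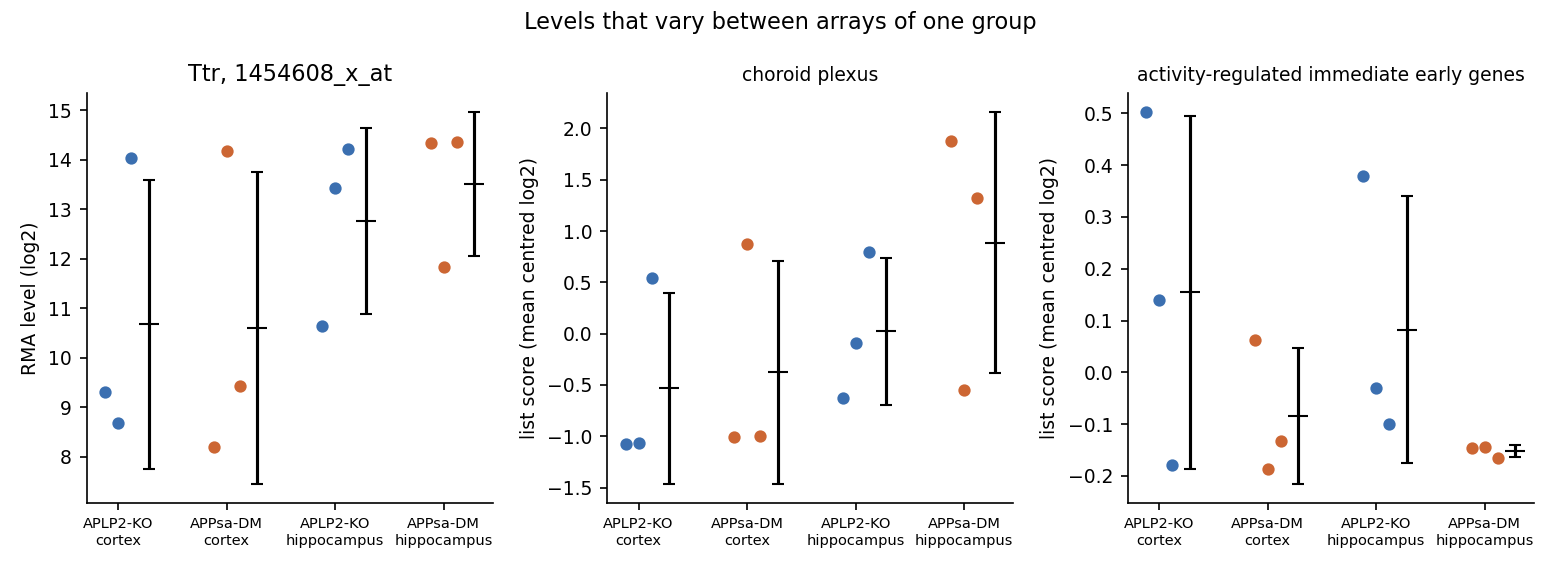
Ttr log2 signal, mean score of the choroid plexus list and mean score of the immediate early genes per array (points), with group mean and SD (bars, n = 3). Ttr runs from 8.20 to 14.36 and varies within every group, with 11.83 as the lowest value in APPsα-DM hippocampus. APLP2-KO replicate 1 has the highest immediate early score in cortex (0.502) and hippocampus (0.378).

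Averaged over both tissues, App fell (probe set 1 by -4.63 ± 0.07, adjusted p = 7.38e-08; probe set 2 by -1.79 ± 0.06, adjusted p = 1.31e-05), the unnamed probe set fell by -3.32 ± 0.08 (adjusted p = 1.33e-06) and Timmdc1 rose by 0.87 ± 0.07 (adjusted p = 0.0256), each over 3 against 3 means. These were the 4 calls, and 1816 probe sets (4.03%) had an unadjusted p under 0.05. Cdk5rap1 (-0.65 ± 0.09, adjusted p = 0.775), Slc35a5 (-0.39 ± 0.06) and Upk1b (-0.44 ± 0.07, adjusted p = 0.841 each), B9d1 (0.41 ± 0.07, adjusted p = 0.989) and Ccdc80 (0.46 ± 0.08, adjusted p = 0.9999) did not pass. The Timmdc1 call ended without APLP2-KO replicate 2 (0.217), APLP2-KO replicate 3 (0.0623), APPsα-DM replicate 1 (0.162), APPsα-DM replicate 2 (0.178) or APPsα-DM replicate 3 (0.0833) and with the choroid covariate (0.105), and its difference stayed between 0.83 and 0.93 over all settings with an adjusted p from 0.000257 to 0.217. Without APLP2-KO replicate 3, 13 probe sets were called instead of 4, of which 3 were among the 4 and several were choroid plexus genes such as Folr1, Aqp1 and Kcne2.

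No gene was called, over all genes, for a genotype effect that differed between the tissues. Limma called 0 of 45037 probe sets, at a median SE of 0.133, the smallest adjusted p was 0.9998 and 1705 (3.79%) had an unadjusted p under 0.05. For App probe set 2 the difference was -0.24 ± 0.10 (adjusted p = 0.9998). Cplane1 (-0.53 ± 0.10), Prokr2 (-0.65 ± 0.13) and Plcd3 (0.41 ± 0.09) had among the smallest p values, with an adjusted p of 0.9998 each.

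The genotype differences of cortex and hippocampus were weakly correlated across 18194 genes (Pearson r = 0.169, Spearman rho = 0.0902), and 53.5% had the same sign. Genes are not independent replicates, and arrays of the tissues can share animals. Genotypes were relabelled in each tissue separately, which breaks any pairing of the tissues by animal. Among 200 such relabellings, 16, the real one included, gave an r as high, and the highest other was 0.322. Among the 9097 genes above the median level, App included, r was 0.358, which 1 of 200 relabellings, the real one, reached, with 0.322 as the highest other. If the tissues share animals, whole animals allow only 10 splits, too few for a share under 0.05. These counts are therefore no test of agreement between the tissues. Without App and the genes listed around it, r was 0.154 (19 of 200 as high, highest other 0.305).

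**Figure D3:**
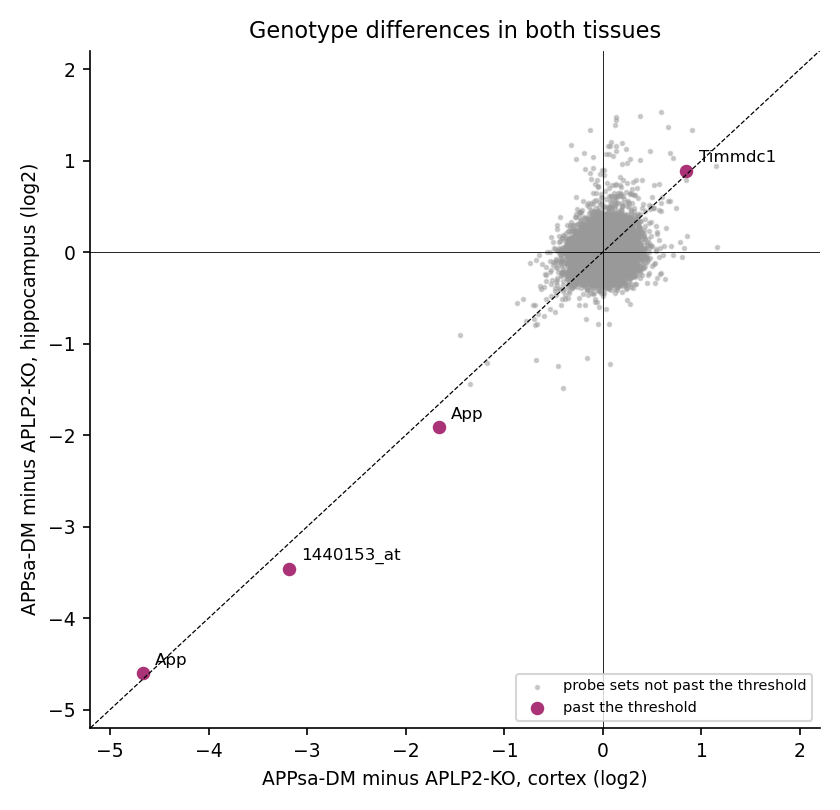
Log2 difference APPsα-DM minus APLP2-KO in cortex (horizontal) against hippocampus (vertical), 1 point per probe set, with the 4 called probe sets in purple. App probe set 1 lies at -4.67 and -4.60 and Timmdc1 at 0.84 and 0.89, while most other probe sets lie near 0 in both tissues.

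Genes close to App were examined because sequence of the strain in which App was edited can remain linked to it after 6 generations of back-crossing. Of 94 genes of the fixed chromosome 16 list, 1, App itself, passed in either tissue, against 1 of 18100 others, Timmdc1 (two-sided Fisher's exact p = 0.0103). Since App is the edited gene, that p says nothing about its neighbours, and with App left out 0 of 93 passed (exact p = 1). The median absolute difference of the list was 0.0642 in cortex, at percentile 77.6 of 10000 random lists matched on level (median 0.0586), and 0.0710 in hippocampus, at percentile 99.6 (median 0.0515). With App left out the percentiles were 73.3 and 99.5. On the whole of chromosome 16 with App left out, 1 of 592 genes passed, Timmdc1, against 0 of 17601 elsewhere, a count made after Timmdc1 was seen to pass (two-sided Fisher's exact p = 0.0325) and so no test of enrichment. Of 35 genes around Aplp2 on chromosome 9, 0 passed against 2 of 18159 others (exact p = 1), and the percentiles were 79.6 in cortex and 84.9 in hippocampus. For the mean effect, the chromosome 9 list stood at percentile 98.5 and the chromosome 16 list at 99.7.

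**Figure D4:**
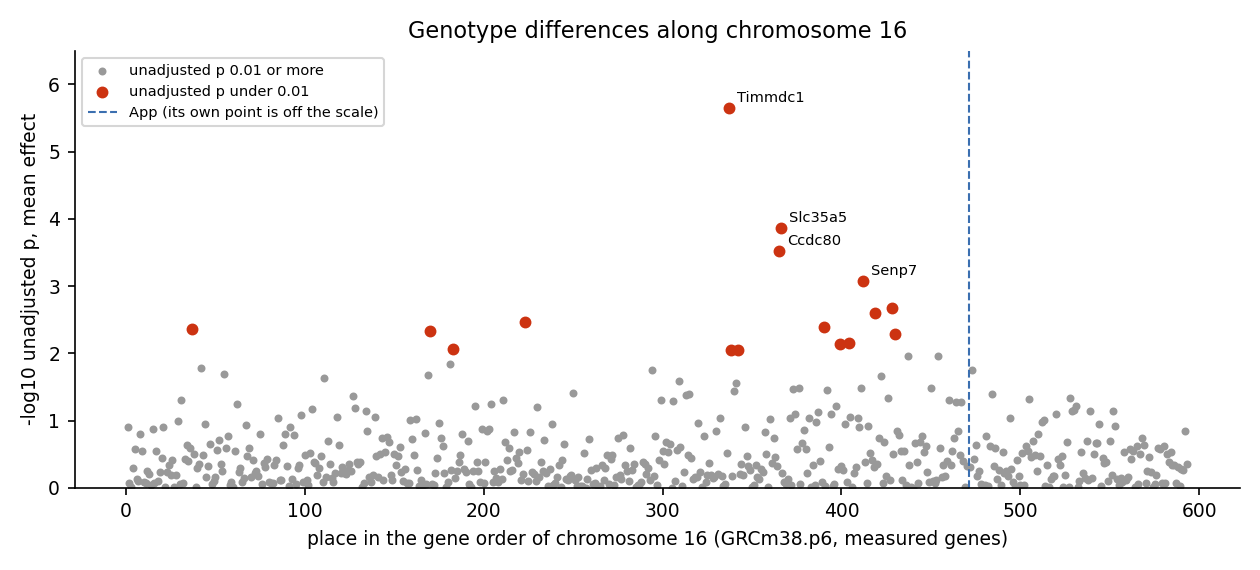
Unadjusted p of the mean genotype effect, as -log10, for 593 genes along chromosome 16 in gene order, with Timmdc1, Slc35a5, Ccdc80 and Senp7 named and the position of App (order 471, own point off the scale) as a dashed line. Of 17 genes with p under 0.01, 12 lie within 100 neighbouring genes that start at Timmdc1 (order 337).

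Hippocampus and cortex differed widely in both genotypes. The fixed list of hippocampal subfield markers, given below, checks the tissue labels. The genes named next as higher in hippocampus were picked for their large rises in these data and so are no such check. The dentate gyrus genes Dsp and C1ql2 were higher by 5.36 ± 0.36 and 4.16 ± 0.16 in APLP2-KO and by 5.02 and 4.61 in APPsα-DM. Npy2r, Lct, Lhx9, Spink8, Fibcd1 and Cabp7 were higher by 4.06, 3.90, 3.69, 3.46, 3.32 and 3.03 in APLP2-KO and by 4.14, 4.11, 3.78, 3.60, 3.16 and 2.93 in APPsα-DM. Lower in hippocampus were Scn4b, a sodium channel gene, by -3.48 ± 0.19 in APLP2-KO and -3.40 in APPsα-DM, Myl4 (-3.38 and -2.94), Rspo1 (-3.18 and -2.99) and the deep-layer marker Foxp2 (-2.90 and -2.73). The dopamine receptor genes Drd2 (-2.79 and -3.16) and Drd1 (-2.63 and -2.41), with Gpr6 (-3.30 and -3.29), Ido1 (-2.51 and -2.99) and Ppp1r1b (-2.54 and -2.42), which mark striatal neurons, were likewise lower in hippocampus. All of these passed in both genotypes (n = 3 each; Dsp adjusted p = 1.03e-06 and 1.91e-06, Scn4b 2.71e-07 and 4.12e-07), and the tissues did not overlap. Whether the cortex pieces held striatal tissue was not tested, so the striatal markers are no check of the cortex label.

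In APLP2-KO, 5672 probe sets of 3536 genes were called between the tissues, 2529 higher in hippocampus and 3143 lower, and 751 of them differed by more than 2-fold. In APPsα-DM, 4789 of 2975 genes were called, 2348 higher and 2441 lower, 667 by more than 2-fold. In both genotypes 1750 were higher (131.8 if independent) and 1994 lower (170.4 if independent), 0 went opposite ways, and the differences correlated at r = 0.873 across probe sets. With number as a block, 5446 were called in APLP2-KO. App probe set 2 was lower in hippocampus of APPsα-DM by -0.24 ± 0.07 (adjusted p = 0.0424), a call lost without APPsα-DM cortex 1 (0.124), hippocampus 1 (0.107), hippocampus 2 (0.141) or cortex 3 (0.113), with array weights (0.0502), with only the 6 arrays compared (0.119) and with the choroid covariate (0.0816). Likewise the unnamed probe set was lower by -0.35 ± 0.10 (adjusted p = 0.0374), lost without APPsα-DM cortex 1 (0.0928), hippocampus 1 (0.136), hippocampus 2 (0.0667) or cortex 3 (0.127), with only the 6 arrays compared (0.112) and with the choroid covariate (0.150). Aplp2 probe set 4 was lower in hippocampus of APLP2-KO by -0.22 ± 0.06 (adjusted p = 0.0458, but 0.0849 with number as a block), lost without any 1 of the 6 APLP2-KO arrays (0.0825 and 0.133 without cortex 1 and hippocampus 1, 0.0685 and 0.117 without cortex 2 and hippocampus 2, 0.153 and 0.0686 without cortex 3 and hippocampus 3), with cyclic loess (0.0579) and with only the 6 arrays compared (0.0937). It differed by -0.21 in APPsα-DM (adjusted p = 0.0580, but 0.0198 without dim probe sets and 0.0215 with a trended robust prior).

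**Figure D5:**
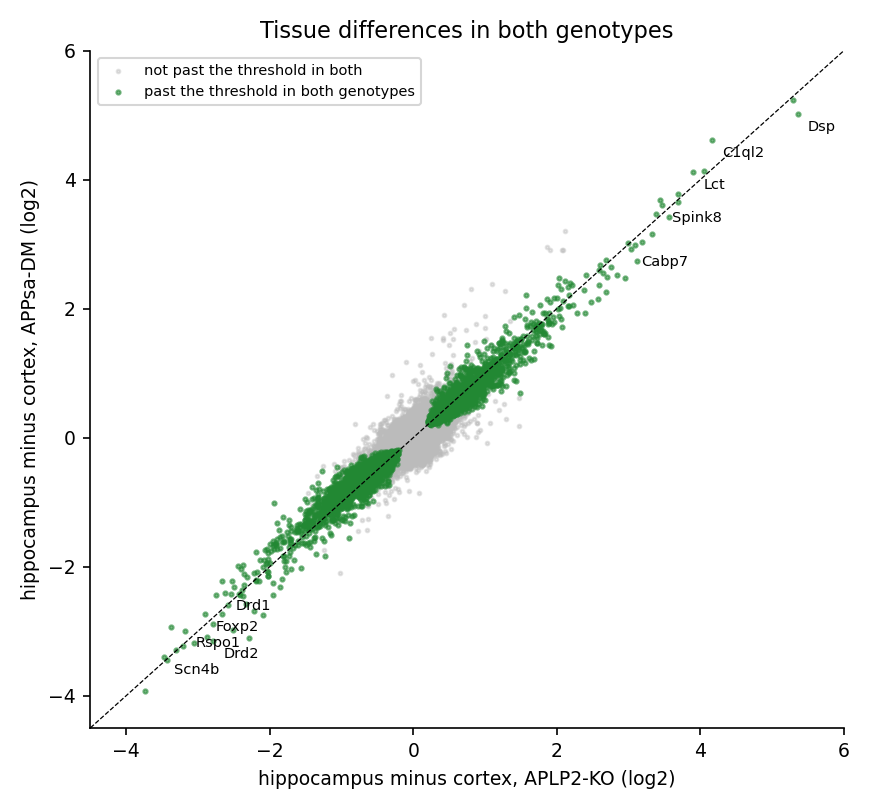
Log2 difference hippocampus minus cortex in APLP2-KO (horizontal) against APPsα-DM (vertical), 1 point per probe set, with named genes such as Dsp (5.36 and 5.02) and Scn4b (-3.48 and -3.40). The probe sets lie along the diagonal (r = 0.873), and 0 are called in opposite directions.

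By gene lists, tested here after the data were seen, hippocampal subfield markers were higher in hippocampus: 21 of 28 rose and 1, Tyro3, fell in each genotype (adjusted p = 1.02e-20 in APLP2-KO and 1.28e-21 in APPsα-DM; adjusted p = 0.0385 and 0.0336 with an estimated correlation). St18 and Kctd4 differed by 1.95 and 1.89 in APLP2-KO. These were the only lists called with an estimated correlation. All 18 striatal markers fell in both genotypes, with medians of -1.95 and -2.24 (adjusted p = 5.5e-23 and 1.43e-26; adjusted p = 0.125 and 0.103 with an estimated correlation). Of 23 cortical layer markers, 14 fell and 3 rose in APLP2-KO and 12 fell and 3 rose in APPsα-DM (adjusted p = 1.51e-06 and 5.28e-06; adjusted p = 0.125 and 0.156 with an estimated correlation), with Lamp5 at -2.06 and -1.75 and Mef2c at -1.58 and -1.38. In APLP2-KO, 7 of 32 lists were called and in APPsα-DM 8 of 32, with 11 and 9 by fry.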

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

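The tests weighed here for chromosome 16, choroid plexus RNA and immediate early genes were chosen only after the results were seen, except those on other splits of the arrays, and so were the choroid covariate and the list tests of the difference between tissues.

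Genotype effects that differed between cortex and hippocampus were called by camera for 3 lists, at the preset correlation only, and for no single gene over all genes. Fry's test for 1 direction called 0 of the 32 lists, with an adjusted p of 0.989 for each of these 3. The endothelial list was higher in APPsα-DM by more in hippocampus than in cortex (adjusted p = 0.0315; adjusted p = 0.980 with an estimated correlation), a difference lost without APLP2-KO cortex 1 (0.347), APLP2-KO hippocampus 3 (0.0722), APPsα-DM cortex 1 (0.133), APPsα-DM hippocampus 1 (0.499) or APPsα-DM cortex 3 (0.132). The choroid plexus list differed the same way (adjusted p = 0.0315; adjusted p = 0.980 with an estimated correlation), and not without APLP2-KO hippocampus 1 (0.386), APLP2-KO hippocampus 2 (0.0570), APLP2-KO cortex 3 (0.484), APPsα-DM cortex 1 (0.133), APPsα-DM hippocampus 1 (0.808), APPsα-DM cortex 3 (0.281) or APPsα-DM hippocampus 3 (0.174). The striatal list differed the other way, higher in APPsα-DM by more in cortex (adjusted p = 0.0315; adjusted p = 0.980 with an estimated correlation), and not without APLP2-KO hippocampus 1 (0.404), APLP2-KO cortex 3 (0.452), APPsα-DM hippocampus 2 (0.0546), APPsα-DM cortex 3 (0.699) or APPsα-DM hippocampus 3 (0.174). With the choroid covariate the difference had an adjusted p of 0.115 for the endothelial list and 0.142 for the striatal list. Synaptic vesicle release and cortical layers were called instead (adjusted p = 0.0455 each at the preset correlation).

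The list APP family and its secretases differed between the tissues in fry's test for change in either direction (adjusted p = 0.0223), and within it Bace2 differed by -0.55 ± 0.14 (adjusted p = 0.0284 over the list alone and 0.9998 over all genes), being 0.36 ± 0.10 in cortex and -0.19 ± 0.10 in hippocampus. Bace2 also stands in the fixed list of genes around App on chromosome 16, examined because strain sequence can remain linked to App.

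Genes of chromosome 16 had an unadjusted p under 0.01 for the mean effect in 17 of 593 cases (2.87%), more than on any other chromosome (next 1.25%, chromosome 11; Fisher's exact p = 7.7e-06, 0.000154 after adjustment over 20 chromosomes; 16 of 592 without App, exact p = 2.73e-05). Of the 17, 12 lay within 100 neighbouring genes that start at Timmdc1 and end before App, where random draws gave a median of 6 and 0 of 10000 gave as many, and the 16 genes other than App lay at a median distance of 105.5 genes from App against 174.5 in random draws, of which 89.6% lay farther. Of these 16 genes, the nearest to App in order was Cldnd1 (order 430, with App at 471), and none lay past App. For the mean effect, the 52 genes within 5 Mb of App, App included, still stood at percentile 98.5 of random lists. The stretch that starts at Timmdc1 could be strain sequence linked to the edited App allele, as a hypothesis. Closeness of its genes to App itself is the weaker part of these values. Probes that hit such sequence could give differences without a change in RNA: of 6 other probe sets of these genes above the median level, 83.3% shared the sign (exact interval 35.9 to 99.6), too few to decide. The 10 splits of the 6 means are too few for a share under 0.05, with 2.87% for the real split and 1.69% as the highest other, and an effect of the APPsα allele itself on this stretch stays open, as untested.

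Choroid plexus genes were higher in APPsα-DM hippocampus at the preset correlation (adjusted p = 0.966 with an estimated correlation, and 0.206 without APPsα-DM hippocampus 1 at the preset one), and choroid plexus tissue carried over in dissection may account for them. Over the deviations of the 12 arrays from their group means, the 22 other genes of that list followed Ttr with a median r of 0.851 (0.326 to 0.962), and both genotypes held arrays with high and low Ttr. The tables argue against the same source for the endothelial list: with the choroid score as a covariate its median in hippocampus was 0.156 instead of 0.175 (24 of 25 genes above 0), and its genes had a median r of -0.0664 with Ttr. A genotype effect on vessels and a share of vessel tissue that differed between dissections both stay open, as untested.

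Immediate early genes were lower in APPsα-DM in both tissues at the preset correlation (adjusted p = 0.867 in cortex and 0.928 in hippocampus with an estimated correlation), with a list mean of -0.237 over both. Without APLP2-KO replicate 1 it was -0.0759, 32.1% of its size, against -0.269 without replicate 2 and -0.366 without replicate 3, so that high levels in APLP2-KO replicate 1 may account for most of it. Yet in hippocampus the list score separated the genotypes (two-sided exact p = 0.1, the smallest possible). APLP2-KO hippocampus 2 and 3 scored -0.0309 and -0.0996 there, against -0.166 to -0.145 in APPsα-DM. In cortex the score did not separate them (exact p = 0.3). The genes of the list also move together between arrays of a group, and neither call held with the correlation estimated. An effect of genotype on neuronal activity stays open, as untested beyond these arrays.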

How the results depend on the processing

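The choroid covariate, the cortex arrays high in Ttr left out, App left out, the whole of chromosome 16 and the list tests of the tissue comparisons were tests chosen only after the results were seen. The counts in cortex (3 to 5), hippocampus (3 to 5), between tissues (4060 to 8428 in APLP2-KO, 3340 to 6619 in APPsα-DM) and for the difference between tissues (0) stayed near those of the main settings. For the mean effect the count ran from 3 to 13 as replicates were left out, and the 13 came without APLP2-KO replicate 3. App probe sets 1 and 2 and the unnamed probe set passed in both tissues and for the mean under every setting. Timmdc1 kept its direction and lost its call in the settings given with it and, for the mean effect, with a replicate block, the cause not tested apart from the smaller number of arrays. Array weights added Bcorl1 in hippocampus, leaving out APLP2-KO hippocampus 1 added Clec14a, all 12 arrays without a block added Cdk5rap1 to the mean effect, and the choroid covariate put Cbln3 in place of Timmdc1. Dim probe sets of App and Aplp2 have no value under the filter on dim signals. Of the other values, 79 lost their call under a setting and 81 with a replicate left out, and 8 and 10 changed direction. Direction and side were kept by 1803 and 1202, which include values that were never called, so these are no measure of how stable the calls were. Signal near the lower end limits App probe set 3, at 2.64.

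Small differences changed sign, the cause not tested. App probe set 3 in hippocampus was -0.0517 with array weights and ran from -0.0539 to 0.123 as replicates were left out. Aplp2 probe set 3 in cortex was 0.0868 without the cortex arrays high in Ttr (-0.180 to 0.0259 as replicates were left out), and probe set 2 in hippocampus -0.0441 with the choroid covariate (-0.0199 to 0.0258). Aplp2 probe set 5 in hippocampus was 0.0340 with cyclic loess, 0.00675 with median centring, 0.0908 with array weights and 0.0408 with the choroid covariate (-0.106 to 0.122). With replicates left out, Aplp2 probe set 1 in cortex ran from -0.0823 to 0.0458 and probe set 2 in cortex from -0.140 to 0.00262.

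Lists called in cortex numbered 0 with the estimated correlation, 2 by fry and 4 to 7 as replicates were left out, against 8. In hippocampus they numbered 0, 2 by fry and 3 with the choroid covariate, and 5 to 9 as replicates were left out (9 without APPsα-DM hippocampus 1), against 6. The adjusted p of the smooth muscle list ran from 1.03e-09 to 0.0465 in hippocampus and from 0.000105 to 0.704 between tissues in APPsα-DM as replicates were left out, with the direction turned without APPsα-DM hippocampus 1. With the choroid covariate the choroid list turned for the difference between tissues (0.983) and between tissues in APPsα-DM (0.970), since the covariate is built from its own genes. The correlation between tissues was 0.358 among genes above the median level. The percentile of genes near App in cortex was 97.3 within 10 Mb, 96.6 within 20 Mb, 98.8 for chromosome 16 and 98.7 without App, and in hippocampus 90.3 within 5 Mb, the cause not tested.

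With a replicate block, cortex gave 5 calls, hippocampus 5 and the mean effect 4, with Timmdc1 lost for the mean (0.131) and another unnamed probe set added in all 3, and the block gave 0 for the difference between tissues and 4477 between tissues in APPsα-DM, where App probe set 2 had 0.0669. The sources do not state that these numbers pair animals. Same-number residuals of the genotypes correlated at -0.0796, -0.255 and -0.126 in cortex and at 0.118, 0.0288 and 0.206 in hippocampus. Among the hippocampus arrays of its own genotype, each of the 6 cortex arrays correlated best with that of its own number. Each APLP2-KO hippocampus array likewise correlated best with the APPsα-DM hippocampus array of its number, which comes from another animal. A match by number therefore does not show a shared animal. A random replicate block (consensus correlation 0.0744) gave 4, 4, 0, 6192, 5329 and 5 for cortex, hippocampus, difference, APLP2-KO, APPsα-DM and mean. In APLP2-KO the block changed no call of a named gene or list other than Aplp2 probe set 4 and the oligodendrocyte list.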

Other observations

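The list tests of hippocampus against cortex and the choroid covariate reported here were tests chosen after the data were seen, whereas the tests on other splits of the arrays and the checks of RNA quality were planned.

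Besides the regional markers, lists of glia, sterol genes, synaptic vesicles and vessels were called between hippocampus and cortex in 1 genotype or both at the preset correlation, and none of these with the estimated correlation. Astrocyte markers were higher in hippocampus: 6 rose and 1 fell of 27 in APLP2-KO and 5 rose and 1 fell in APPsα-DM (adjusted p = 0.0200 and 0.00368; adjusted p = 0.907 and 0.920 with an estimated correlation). Gfap, the filament of reactive astrocytes, rose by 1.18 and 1.38 and Aqp4 by 0.61 and 0.54, while Aldh1l1 was lower by -0.45 and -0.42. Without APLP2-KO cortex 3 the astrocyte call was lost in APLP2-KO (0.104). Genes of cholesterol synthesis and uptake were lower in hippocampus, 6 of 23 in each genotype, with Insig1 at -0.56 and -0.47 (adjusted p = 0.00881 and 0.00152; adjusted p = 0.907 and 0.920 with an estimated correlation), and the APLP2-KO call was lost without APLP2-KO hippocampus 3 (0.0554). Synaptic vesicle release was called lower in APLP2-KO, where 10 fell and 3 rose of 39 (adjusted p = 0.010; adjusted p = 0.907 with an estimated correlation), and had an adjusted p of 0.0755 in APPsα-DM. Among genes of GABAergic neurons and synapse, Npy (-1.03 and -0.85) and Vip (-1.12 and -0.83) were lower and Gabra5 (1.97 and 1.80) was higher in hippocampus of APLP2-KO and APPsα-DM, with the list itself not called (adjusted p = 0.108 and 0.0603). Among glutamatergic postsynapse genes Gria1 was higher (1.35 and 1.30) and Dlg4 lower (-1.09 and -0.69), and the list was not called either (adjusted p = 0.851 and 0.894).

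Endothelial and pericyte markers were lower in hippocampus of APLP2-KO, where 5 of 25 fell (adjusted p = 0.0272; adjusted p = 0.952 with an estimated correlation), a call lost without APLP2-KO cortex 1 (0.159) and APLP2-KO hippocampus 3 (0.0554) and by fry (0.0909), and not called in APPsα-DM (0.540). In APPsα-DM the lists higher in hippocampus included choroid plexus, with a median of 1.12 and 0 of 23 members past the threshold (adjusted p = 0.000906; adjusted p = 0.965 with an estimated correlation; 0.0941 without APPsα-DM hippocampus 1, 0.970 and turned with the choroid covariate, 0.326 by fry). Smooth muscle, leptomeninges and fibroblasts was also higher, with 3 of 23 risen, among them Dcn at 2.30 (adjusted p = 0.0204; adjusted p = 0.965 with an estimated correlation), and had an adjusted p of 0.704 with the direction turned without APPsα-DM hippocampus 1 and 0.0625 without APPsα-DM cortex 3, 0.231 with the choroid covariate and 0.326 by fry. Oligodendrocyte and myelin markers lay lower in hippocampus of APPsα-DM, 25 of 26 below 0 (adjusted p = 0.0426; adjusted p = 0.965 with an estimated correlation), a call lost without APPsα-DM hippocampus 1 (0.153), cortex 2 (0.211), cortex 3 (0.0981) or hippocampus 3 (0.161), with the mean of all probe sets of a gene (0.0527), with the choroid covariate (0.397) and by fry (0.424). In APLP2-KO the oligodendrocyte list had an adjusted p of 0.108, and 0.0117 with number as a block. The smooth muscle score was 1.09 on APPsα-DM hippocampus 1 and lay between -0.172 and 0.169 on the other hippocampus arrays.

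For the mean genotype effect over both tissues, 9 lists were called at the preset correlation and 0 with the estimated one, whose smallest adjusted p was 0.718. Higher were endothelial cells and pericytes (adjusted p = 5.06e-09), choroid plexus (1.71e-06), striatal neurons (0.000302), smooth muscle (0.00116), GABAergic neurons and synapse (0.00579) and the respiratory chain (0.0149). Lower were cholesterol synthesis and uptake (7.09e-11, 21 of 23 below 0), immediate early genes (1.1e-05) and astrocytes (0.0149). Adjusted over the list alone, the endothelial gene Itm2a was higher by 0.26 ± 0.06 (adjusted p = 0.0442), the thalamic marker Tnnt1 was lower by -0.41 ± 0.09 (adjusted p = 0.0406), and App was lower, while the thalamic list itself was not called (adjusted p = 0.703).

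Xist, expressed from the inactive X chromosome, read 10.6 to 11.3 on every array, and the Y-linked genes Eif2s3y, Kdm5d and Uty read 2.44 to 3.73, as the labels' female animals would give. The signal of Actb probe sets near the 3' end exceeded that of the 5' end by 0.91 to 1.33 log2 units over the arrays and did not separate the genotypes in cortex (two-sided exact p = 0.5) or hippocampus (exact p = 0.9), and for Gapdh it lay between -0.11 and 0.04 (exact p = 0.5 and 0.6).

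Other splits of the arrays were tested for each count. The 6 cortex arrays, the 6 hippocampus arrays and the 6 means each have 10 splits, too few for a share under 0.05. The real split called 4 probe sets in cortex (highest other 1), 4 in hippocampus (highest other 2) and 4 for the mean effect (highest other 5). It called 5672 between the tissues in APLP2-KO and 4789 in APPsα-DM, each with a highest other of 0. In APLP2-KO, where same-number residuals correlated above 0.1, the other splits that part every same-number pair also gave 0. For the difference between tissues, the real count was 0, which each of 100 drawn splits (highest other 9) reaches whatever the data, so that the splits say nothing about chance there. Lists called at the preset correlation numbered 8 in cortex and 6 in hippocampus, with a highest other of 13 in each. As many or more were called by 8 of 10 cortex splits and 9 of 10 hippocampus splits, the real one included. Most splits that mix the genotypes thus gave at least as many list calls as the genotypes did.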
